A study of Drosophila melanogaster with 18 samples.

How the data were processed

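RNA came from whole adult female flies, 1 to 5 days old, raised at 25 °C on a mashed potato diet, per the labels' protocols. Each of 18 libraries was made from 10 flies, with 3 biological replicates in each of 6 groups (control or Tudor-SN knockdown, in normoxia, 6% O2 or 2% O2). Polyadenylated RNA was taken with poly-dT beads and sequenced on a BGISEQ-500, per the labels. The labels do not state whether libraries were strand-specific, so reads of genes that overlap on opposite strands may not have been told apart. Groups were taken from the sample titles and genotypes.

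The authors deposited 1 table per library with the FPKM of 17658 genes, made with Cufflinks, and TopHat2 and HTSeq are also named, on build BDGP6, per the submitters' processing notes. No version of these tools is given in the sources used here. FPKM divides the fragments assigned to a gene by its length and by the library's total, so a value is relative to all other transcripts of that library, and a large change in abundant genes shifts the rest. Cufflinks also divides reads among overlapping and nearly identical genes by its own model. Values of the Hsp70 copies, Cyp12d1-p and Cyp12d1-d and other near-identical pairs are therefore uncertain one by one. All 38 genes of the mitochondrial genome are listed at 0 in every library, so an exact 0 does not show that a transcript was missing. Gene symbols are those of the deposited tables. Of the gene identifiers, 17521 were found in the reference annotation, 17303 with identical coordinates, and coordinates are printed as deposited. No column of other samples was found (0 not used). Any 2 libraries shared at most 2 identical values above 0.

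FPKM carries no read total. Low values of a gene across libraries are nearly whole multiples of what 1 read is worth, which gave a relative depth per library: factors from 0.7 to 1.4 in steps of 0.005 were scanned. At the best factor 74.3% to 81.6% of the 898 to 1099 low values used per library lay within 0.04 of a whole multiple. Genes were used only if enough of their unscaled values already lay near whole multiples of a common unit. That choice partly sets this share and could draw the factors toward 1. This way of estimating depth replaced an earlier one after its first values had been seen. Relative depth was near 1 in all libraries but knockdown 2% O2 replicate 3 (0.87). Low genes there carry more counting error.

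FPKM were divided by median-of-ratios factors, computed over 9068 genes above 1 FPKM in every library, which ranged from 0.947 to 1.04. The knockdown 2% O2 libraries had the lowest factors (0.965, 0.977 and 0.947), so scaling goes along with that group. A gene was tested where its mean over all libraries was at least 1 FPKM, which left 9921. Log2 of scaled FPKM plus a pseudocount of 1 was fitted with limma 3.58.1 in R 4.3.3, with 6 group means, all 18 libraries sharing 1 estimate of the spread, and eBayes with trend and robust options. The 11 comparisons were knockdown against control at each oxygen level, each pair of oxygen levels within each genotype, and the differences between genotypes in the response to 6% O2 and to 2% O2. P values were adjusted by Benjamini-Hochberg within each comparison, and a result was called at an adjusted p under 0.05. Tudor-SN was also compared by 2-sided exact permutation tests.

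Of 34 gene lists 33 had at least 3 tested members and were tested with camera at its preset correlation of 0.01. The list of male accessory-gland and testis genes, included as a check of sex, had 2 tested members and was not tested. In all, 1149 list entries matched a gene and 17 did not. Camera with an estimated correlation and fry were run beside it. Of 172 list calls over the 11 comparisons none held with an estimated correlation (0 with an adjusted p under 0.05), and 92 were also called by fry, which tests whether a list's genes move one way and not against other genes and called 102 in all. A list score is the mean over its members of log2 levels centred on each gene's mean.

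Genes named in the text were taken by a fixed rule. In every comparison these were Tudor-SN and, among called genes whose 3 values in one group all lay above those of the other (not required for differences of responses) and whose higher group mean was at least 2 scaled FPKM, the 8 largest changes each way for knockdown against control in normoxia and for control flies at 6% O2 and 2% O2, and the 5 largest each way elsewhere. From each called list up to 4 members with the smallest adjusted p were taken, from other lists up to 2, and ImpL3, scyl, the Hsp70 copies, AttA, TotA and Yp1 were fixed. The lists, this rule, the comparisons, the test and the alternatives were set before the data were examined, except the alternative without 104 loci under 300 bp, which was added afterwards.

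Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, FPKM as deposited, quantile normalisation, a replicate block, a fit of only the groups compared, eBayes without trend and robust, array weights, and leaving out each library in turn. With 1 library left out an arm keeps 2, whose spread is taken from all groups. Values were read and drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

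The steps were tested on simulated data. For knockdown against control in normoxia over 9921 genes, 30%, 72%, 98% and 98% of 50 genes each, changed by log2 0.25, 0.5, 1 and 2, were called, as were 7 of 9721 unchanged genes. For control flies at 2% O2 with no gene changed, 0 of 9921 were called by limma. Camera called a list of 30 genes shifted by 0.3 and did not call an unchanged list of 30. The simulated noise was independent between genes. These runs therefore do not show how correlation between genes affects list calls or counts of called genes.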

Results

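Transcript levels were measured by sequencing polyadenylated RNA from whole adult female *Drosophila melanogaster*. Control flies carried an RNAi transgene against Tudor-SN with no driver, and knockdown flies carried it together with daughterless-GAL4, a driver active in nearly all tissues. Tudor-SN is an RNA-binding protein found in the RNA-induced silencing complex and in stress granules. Flies of each genotype stayed in room air (normoxia) or spent 6 h in 6% O2 or 2% O2, which makes 6 groups of 3 libraries, each from a pool of 10 flies. The questions are which transcripts differ between knockdown and control flies at each oxygen level, which respond to low oxygen in each genotype, and whether the genotypes respond differently. Flies with the driver alone were not analysed here, so a difference between knockdown and control flies may come from the driver or its background as well as from the loss of Tudor-SN.

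The deposited values were FPKM, which sum to 876999 to 1000923 per library, with 12525 to 12951 genes above 0. Read totals are not part of the values. The spacing of low values put the relative depth of the libraries between 0.955 and 1.015, except for knockdown 2% O2 replicate 3 at 0.87. The 10 most abundant genes took 7.52% to 9.14% of the summed FPKM, with the highest shares in the knockdown 2% O2 libraries (8.79%, 8.53% and 9.14%). The first principal component (44.2% of the variance) set the 2% O2 libraries apart and the second (14.1%) the genotypes, where knockdown 2% O2 replicate 3 lay at 0.95 against -15.5 and -16.8 for replicates 1 and 2. In all, 9921 genes with a mean of at least 1 FPKM were tested with limma, and a gene is named as called where its Benjamini-Hochberg adjusted p was under 0.05. Changes are log2 differences of scaled FPKM plus 1, which understates the change of low genes, and are given ± SE with n = 3 per group.

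Tudor-SN itself (FBgn0035121, BDGP6 chromosome 3L, 259043 to 264380) was at 214 ± 4.15 scaled FPKM in control flies in normoxia (SD, n = 3), 217 ± 3.22 at 6% O2 and 168 ± 6.55 at 2% O2. In knockdown flies the levels were 19.9 ± 1.43, 15.9 ± 2.20 and 5.56 ± 0.449, which are 9.28%, 7.33% and 3.32% of the control level at the same oxygen. The log2 differences between genotypes were -3.37, -3.70 and -4.68 ± 0.0771 (limma adjusted p = 1.41e-13, 3.38e-14 and 8.97e-16), and no knockdown library overlapped a control library. A 2-sided exact permutation test between the genotypes at each oxygen level gave p = 0.1, the smallest value that 3 against 3 libraries allow. At 2% O2 Tudor-SN fell to 28.0% of its normoxia level in knockdown flies (log2 -1.67 ± 0.0771, adjusted p = 3.28e-10) and to 78.3% in control flies (log2 -0.35 ± 0.0771, adjusted p = 0.00260). The 2 falls differed (difference of log2 changes -1.32 ± 0.109, adjusted p = 2.74e-05). At 6% O2 the log2 change was -0.31 in knockdown flies (adjusted p = 0.111) and 0.02 in control flies (adjusted p = 0.93), neither of which passed the test. The change in knockdown flies passed with array weights (-0.294, adjusted p = 0.0139) and without knockdown 6% O2 replicate 1 (-0.404, adjusted p = 0.0384).

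**Figure D1:**
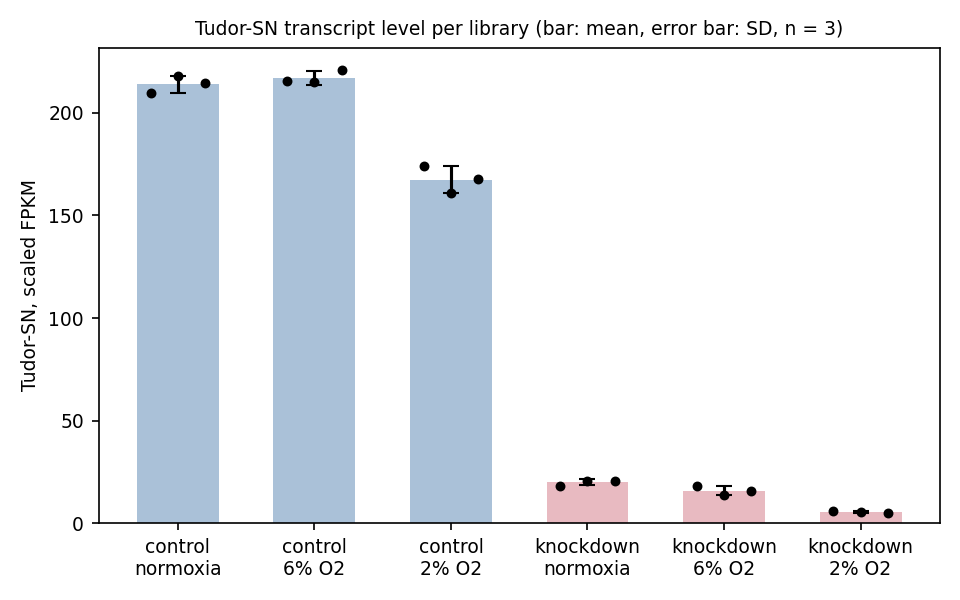
Tudor-SN level in scaled FPKM (vertical axis) for the 6 groups (horizontal axis). Bars are group means, error bars the SD and points the 3 libraries of each group. The 9 knockdown libraries lie far below the 9 control libraries, and the knockdown libraries at 2% O2 (5.56 ± 0.449) lie below those in normoxia (19.9 ± 1.43).

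In control flies, 6 h at 2% O2 raised lactate dehydrogenase, the FGF ligand bnl and the Hsp70 chaperones. Lactate dehydrogenase, listed as ImpL3, which regenerates NAD+ for glycolysis, went from 6.21 ± 0.628 to 99.4 ± 9.12 scaled FPKM (SD, n = 3). This is a log2 change of 3.80 ± 0.198 (limma adjusted p = 1.34e-08). The gene bnl, which guides tracheal branches, rose by 2.24 ± 0.117 (adjusted p = 4.77e-09). The Hsp70 copies, inducible chaperones, rose by between 3.64 ± 0.187 (Hsp70Aa) and 4.29 ± 0.115 (Hsp70Bb). These copies are nearly identical in sequence, so how reads were divided among them is uncertain. Apart from the Hsp70 copies, the largest rises were in CG34040 (5.14 ± 0.566), CG15829 (4.58 ± 0.541) and the non-coding CR44138 (4.20 ± 0.257), and the frost gene Fst rose by 4.06 ± 0.610.

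Many genes for stress defence rose. In the list of heat-shock proteins and chaperones 14 of 24 members rose and 0 fell (14 adjusted over the list alone; camera adjusted p = 2.75e-10, and adjusted p = 0.0564 with an estimated correlation). Of the 18 hypoxia-response genes 13 rose and 0 fell (15 adjusted over the list alone; camera adjusted p = 1.13e-09, and adjusted p = 0.0564 with an estimated correlation). The prolyl hydroxylase Hph (0.61 ± 0.0576) and the translation inhibitor Thor (1.52 ± 0.158) were examples, and scyl rose by 0.41 ± 0.0621. Oxidative-stress and glutathione genes had 18 of 35 members up and 3 down (19 and 3 adjusted over the list alone; camera adjusted p = 2.28e-06, and adjusted p = 0.0945 with an estimated correlation). The glutathione transferases GstD2 (3.06 ± 0.225) and GstD5 (2.28 ± 0.132) were examples. Apoptosis and stress-signalling genes had 13 of 20 up and 0 down (14 adjusted over the list alone; camera adjusted p = 2.47e-07, and adjusted p = 0.0945 with an estimated correlation). The JNK-pathway genes Ets21C (2.41 ± 0.188) and puc (0.95 ± 0.0834) and the transcription factor Xrp1 (1.11 ± 0.136) also rose. Autophagy genes had 8 of 21 up and 0 down (8 adjusted over the list alone; camera adjusted p = 0.00186, and adjusted p = 0.0945 with an estimated correlation). Atg8a (0.59 ± 0.0838) was an example.

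Some genes of fasting and fat metabolism also rose in control flies at 2% O2. Insulin, FOXO and adipokinetic-hormone genes had 11 of 25 members up and 1 down (13 and 2 adjusted over the list alone; camera adjusted p = 0.00188, and adjusted p = 0.374 with an estimated correlation). The glucosidase tobi changed by 2.79 ± 0.397. Lipid genes had 13 of 25 up and 2 down (14 and 2 adjusted over the list alone; camera adjusted p = 0.000209, and adjusted p = 0.141 with an estimated correlation). The lipase bmm (0.53 ± 0.0512), the phosphatidate phosphatase Lpin (0.82 ± 0.0905) and the carnitine palmitoyltransferase whd (0.41 ± 0.0497) also rose. The glycolysis list did not pass the test (5 up and 1 down of 23, camera adjusted p = 0.0772), nor did the oxidative phosphorylation list (0 up and 1 down of 68, camera adjusted p = 0.999).

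Most ribosome biogenesis genes and digestive proteases fell, as did a few eggshell genes. Of 32 ribosome biogenesis genes 26 fell and 1 rose (26 and 2 adjusted over the list alone; camera adjusted p = 1.23e-10, and adjusted p = 0.0945 with an estimated correlation). The RNA polymerase I subunit RpI135 (-0.61 ± 0.0501) and the nucleolar proteins NHP2 (-0.61 ± 0.0593) and Nop56 (-0.41 ± 0.0443) were examples. Mitochondrial ribosomal proteins had 26 of 72 down and 0 up (30 adjusted over the list alone; camera adjusted p = 2.47e-07, and adjusted p = 0.279 with an estimated correlation). Of 31 digestive proteases 17 fell and 0 rose (21 adjusted over the list alone; camera adjusted p = 5.31e-07, and adjusted p = 0.485 with an estimated correlation). Ser8 changed by -2.43 ± 0.182 and Jon74E by -1.77 ± 0.153. Stress-granule and mRNA-decay genes had 8 of 23 down and 2 up (11 and 2 adjusted over the list alone; camera adjusted p = 0.00402, and adjusted p = 0.485 with an estimated correlation). rin, the fly G3BP, changed by -0.43 ± 0.0747 and Upf2 by -0.43 ± 0.0823. Among eggshell genes 5 of 25 fell and 0 rose (5 adjusted over the list alone; camera adjusted p = 0.0135, and adjusted p = 0.769 with an estimated correlation). The vitelline-membrane gene Vm26Ab changed by -4.77 ± 0.625. The eggshell list call was lost without control normoxia replicate 3 (adjusted p = 0.0795). The eggshell score per library spread widely within groups, for example -1.03, -0.03 and 1.26 in the 3 control normoxia libraries.

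In all, 2988 genes were called between 2% O2 and normoxia in control flies, 1530 higher and 1458 lower, of which 235 rose and 122 fell at least 2-fold. For 2915 of them the 3 libraries of one group all lay above those of the other. Without a difference this would hold for 10% of genes, but genes called by a small p are chosen toward it. Such counts, here and below, are therefore no separate support for the calls. Cytosolic ribosomal proteins were called higher (9 up and 1 down of 86, 0 and 1 adjusted over the list alone, camera adjusted p = 8.26e-05, and adjusted p = 0.788 with an estimated correlation), a call that quantile normalisation ended (adjusted p = 0.235).

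At 6% O2 no single gene was called in control flies by limma (1329 genes at an unadjusted p under 0.05). ImpL3 differed from normoxia by 1.09 ± 0.198 with adjusted p = 0.104, which did not pass the test. Some lists were called as a whole although 0 of their members passed over all genes. The oxidative phosphorylation list was lower (median log2 -0.18, 0 members adjusted over the list alone, camera adjusted p = 2.32e-13, and adjusted p = 0.727 with an estimated correlation). The hypoxia-response list was higher (median 0.08, 4 members up adjusted over the list alone, camera adjusted p = 0.000218, and adjusted p = 0.727 with an estimated correlation), as was ribosome biogenesis (median 0.09, 5 up adjusted over the list alone, camera adjusted p = 3.31e-06, and adjusted p = 0.727 with an estimated correlation). The eggshell list was higher (median 0.49, 3 up adjusted over the list alone, camera adjusted p = 7.75e-06, and adjusted p = 0.727 with an estimated correlation) and the cuticle list lower (median -0.31, 5 down and 1 up adjusted over the list alone, camera adjusted p = 0.000180, and adjusted p = 0.727 with an estimated correlation). Between 2% O2 and 6% O2 3184 genes were called in control flies (1674 higher, 1510 lower at 2% O2), including ImpL3 (2.71 ± 0.198), Hsp70Bb (4.04 ± 0.115) and Vm26Ab (-5.05 ± 0.625). Of 32 ribosome biogenesis genes 27 were lower and 1 higher at 2% O2 than at 6% O2 (27 and 1 adjusted over the list alone, camera adjusted p = 3.52e-15, and adjusted p = 0.0890 with an estimated correlation). Heat-shock genes had 15 of 24 higher and 0 lower (15 and 1 adjusted over the list alone, camera adjusted p = 9.58e-11, and adjusted p = 0.0776 with an estimated correlation).

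In normoxia, knockdown flies had less of nearly every nuclear-encoded transcript of mitochondrial oxidative phosphorylation. Of 68 subunits tested 64 were lower and 0 higher than in control flies (65 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.35e-27, and adjusted p = 0.569 with an estimated correlation), with a median log2 difference of -0.46. Examples were the complex I subunits ND-23 (-0.61 ± 0.0792, adjusted p = 0.000317) and ND-B14 (-0.74 ± 0.114). TCA-cycle genes had 9 of 21 members lower and 1 higher (13 and 1 adjusted over the list alone; camera adjusted p = 1.67e-05, and adjusted p = 0.569 with an estimated correlation). SdhB (-0.52 ± 0.110) was an example. Glycolysis genes had 11 of 23 lower and 0 higher (13 adjusted over the list alone; camera adjusted p = 3.72e-05, and adjusted p = 0.569 with an estimated correlation). The hexokinase Hex-C differed by -0.61 ± 0.135. The oxidative phosphorylation score, the mean centred log2 level of the list, was -0.23, -0.28 and -0.25 in the knockdown libraries and 0.31, 0.14 and 0.26 in the control libraries.

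Some markers of gut, muscle, eye and cuticle were lower as well in knockdown flies in normoxia. Gut maltases, amylases and lysozymes had 11 of 19 lower and 0 higher (16 adjusted over the list alone; camera adjusted p = 5.57e-07, and adjusted p = 0.569 with an estimated correlation). Mal-A1 differed by -1.94 ± 0.343. Muscle structural genes had 10 of 27 lower and 0 higher (12 adjusted over the list alone; camera adjusted p = 2.53e-06, and adjusted p = 0.607 with an estimated correlation). The myofilament gene Mf differed by -1.34 ± 0.266. Muscle scores were -0.29, -0.31 and -0.06 in knockdown and 0.72, -0.04 and 0.32 in control libraries. Photoreceptor genes had 12 of 25 lower and 0 higher (16 and 1 adjusted over the list alone; camera adjusted p = 4.98e-06, and adjusted p = 0.569 with an estimated correlation). The arrestins Arr1 (-0.58 ± 0.105) and Arr2 (-0.58 ± 0.106) were examples. Cuticle proteins had 8 of 32 lower and 0 higher (9 adjusted over the list alone; camera adjusted p = 8.49e-05, and adjusted p = 0.569 with an estimated correlation). Cpr65Au differed by -1.03 ± 0.160. Cytochrome P450 genes, which include enzymes of detoxification, had 21 of 68 lower and 1 higher (28 and 2 adjusted over the list alone; camera adjusted p = 4.98e-06, and adjusted p = 0.569 with an estimated correlation). Cyp28d1 differed by -1.70 ± 0.226 and Cyp6d4 by 0.80 ± 0.132.

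Lists of RNA silencing, mRNA decay and germline genes were called higher in knockdown flies in normoxia at the preset correlation of camera, with few members called. Stress-granule and mRNA-decay genes had 5 of 23 higher and 0 lower (9 adjusted over the list alone; camera adjusted p = 0.000101, and adjusted p = 0.569 with an estimated correlation). Small-RNA and silencing genes, without Tudor-SN, had 2 of 16 higher and 0 lower (5 adjusted over the list alone; camera adjusted p = 0.00801, and adjusted p = 0.569 with an estimated correlation). Female germline genes had 6 of 41 higher and 2 lower (12 and 4 adjusted over the list alone; camera adjusted p = 0.00547, and adjusted p = 0.761 with an estimated correlation). osk, the germ-plasm organiser, differed by 0.31 ± 0.0559. Cytosolic ribosomal proteins had 0 of 86 higher and 3 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.00689, and adjusted p = 0.761 with an estimated correlation) with a median of -0.07, which quantile normalisation turned to 0.03 (adjusted p = 0.437). Without control normoxia replicate 3 that list was not called either (adjusted p = 0.607).

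Among single genes, those most raised in normoxia included CG32198 (3.21 ± 0.503), CG17234 (2.55 ± 0.273), the receptor otk2 (1.93 ± 0.133, adjusted p = 5.22e-07) and the copper importer Ctr1B (1.92 ± 0.214). The most lowered, apart from Tudor-SN, included the carboxylesterase Est-6 (-2.36 ± 0.141, adjusted p = 1.63e-07), CG15199 (-2.52 ± 0.367), CG6839 (-2.21 ± 0.310) and CG3819 (-2.18 ± 0.293). AttA (0.21 ± 1.04), TotA (0.25 ± 0.941), Yp1 (0.15 ± 0.282) and ImpL3 (-0.31 ± 0.198) were not called, with adjusted p from 0.276 to 0.903. In all, 1589 genes were called, 585 higher and 1004 lower, of which 20 and 72 differed at least 2-fold, and 1549 had groups that did not overlap. The higher share was 36.8%, and 53.6% with quantile normalisation. The count depended on single libraries: it was 607 and 692 without control normoxia replicates 3 and 1, and 716, 744 and 1019 without knockdown normoxia replicates 1, 2 and 3.

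**Figure D2:**
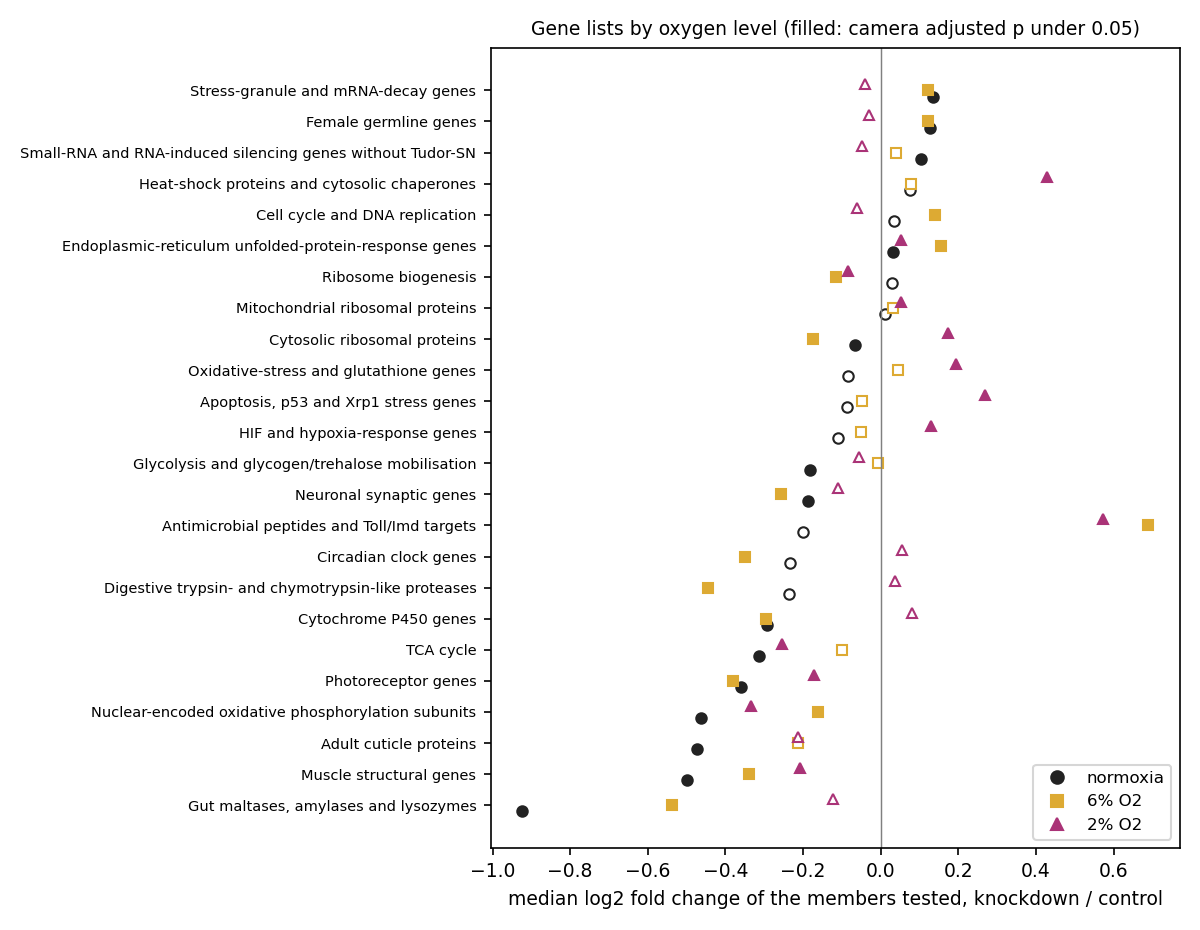
Median log2 difference between knockdown and control flies (horizontal axis) for the gene lists called at one or more oxygen levels (vertical axis). Circles are normoxia, squares 6% O2 and triangles 2% O2, and filled symbols passed the camera test with its preset correlation. Gut enzymes lie lowest in normoxia (-0.92), and the cytosolic ribosomal proteins lie at -0.07 in normoxia, where quantile normalisation turns them to 0.03, at -0.17 at 6% O2 and at 0.17 at 2% O2.

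At 6% O2, the differences between knockdown and control flies included some immune peptides, endoplasmic-reticulum chaperones, ribosomal proteins and eye genes. Antimicrobial and Toll or Imd target genes had 11 of 35 members higher and 3 lower (13 and 3 adjusted over the list alone; camera adjusted p = 0.00460, and adjusted p = 0.758 with an estimated correlation). The bomanin IM23 differed by 4.11 ± 0.589 (adjusted p = 0.000851), the cecropin CecA2 by 3.42 ± 0.714 and IM2 by 2.97 ± 0.611. The immune score was 0.95, 0.37 and 1.70 in the knockdown libraries and 1.02, -0.59 and -0.77 in the control libraries. The immune list call was lost without knockdown 6% O2 replicate 3 (adjusted p = 0.0719) or control 6% O2 replicate 3 (adjusted p = 0.0604). Unfolded-protein-response genes of the endoplasmic reticulum had 15 of 28 higher and 0 lower (17 adjusted over the list alone; camera adjusted p = 8.3e-06, and adjusted p = 0.391 with an estimated correlation). P58IPK (0.27 ± 0.0418), Manf (0.33 ± 0.0609) and the translocon subunit Sec61beta (0.41 ± 0.0590) were examples. Cytosolic ribosomal proteins had 34 of 86 lower and 0 higher (58 lower and 1 higher adjusted over the list alone; camera adjusted p = 4.11e-11, and adjusted p = 0.758 with an estimated correlation), a call that quantile normalisation ended (adjusted p = 0.0572). Ribosome biogenesis genes had 12 of 32 lower and 0 higher (14 adjusted over the list alone; camera adjusted p = 0.000148, and adjusted p = 0.758 with an estimated correlation). RpI135 differed by -0.34 ± 0.0501.

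Several further lists were lower in knockdown flies at 6% O2. Photoreceptor genes had 16 of 25 lower and 0 higher (18 adjusted over the list alone; camera adjusted p = 3.26e-06, and adjusted p = 0.758 with an estimated correlation). Arr2 differed by -0.64 ± 0.106. Cytochrome P450 genes had 22 of 68 lower and 1 higher (28 and 3 adjusted over the list alone; camera adjusted p = 6.67e-06, and adjusted p = 0.758 with an estimated correlation). Cyp6a9 differed by -1.20 ± 0.124. Oxidative phosphorylation had 6 of 68 lower and 0 higher (4 adjusted over the list alone; camera adjusted p = 3.09e-05, and adjusted p = 0.758 with an estimated correlation), with scores of -0.11, -0.09 and -0.26 against 0.08, 0.03 and 0.04. Muscle structural genes had 5 of 27 lower and 0 higher (2 adjusted over the list alone; camera adjusted p = 0.00460, and adjusted p = 0.758 with an estimated correlation), which was lost without knockdown 6% O2 replicate 3 (adjusted p = 0.0546). Circadian clock genes had 6 of 12 lower and 1 higher (8 and 2 adjusted over the list alone; camera adjusted p = 0.0246, and adjusted p = 0.758 with an estimated correlation). The neuropeptide Pdf differed by -0.76 ± 0.110 and the photoreceptor cry by -0.41 ± 0.0930. Digestive proteases had 10 of 31 lower and 0 higher (10 and 1 adjusted over the list alone; camera adjusted p = 0.00191, and adjusted p = 0.758 with an estimated correlation), which was lost without control 6% O2 replicate 1 (adjusted p = 0.0825). Est-6 was again lower (-2.21 ± 0.141), and ImpL3 was level with control flies (0.00 ± 0.198, adjusted p = 1.00). In all, 2448 genes were called (1194 higher, 1254 lower, 48 and 61 of them at least 2-fold), and 2358 had groups that did not overlap. The count was 887 without control 6% O2 replicate 1, and 946 and 1308 without knockdown 6% O2 replicates 2 and 3.

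At 2% O2, knockdown flies had higher levels of many chaperones and antioxidant enzymes and of lactate dehydrogenase than control flies kept at the same oxygen. ImpL3 was at 190 ± 33.1 scaled FPKM (SD, n = 3) against 99.4 ± 9.12 in control flies, a log2 difference of 0.92 ± 0.198 (limma adjusted p = 0.00530). Heat-shock genes had 16 of 24 members higher and 1 lower (18 and 1 adjusted over the list alone; camera adjusted p = 2.09e-11, and adjusted p = 0.0625 with an estimated correlation). The Hsp70 copies differed by between 1.60 ± 0.143 (Hsp70Bc) and 2.10 ± 0.187 (Hsp70Aa). Oxidative-stress and glutathione genes had 17 of 35 higher and 2 lower (18 and 2 adjusted over the list alone; camera adjusted p = 7.64e-08, and adjusted p = 0.137 with an estimated correlation). GstD5 differed by 1.66 ± 0.132 and the ferritin subunit Fer1HCH by 0.55 ± 0.0804. Hypoxia-response genes had 5 of 18 higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.00630, and adjusted p = 0.860 with an estimated correlation). The gene bnl differed by 0.73 ± 0.117, the pyruvate dehydrogenase kinase Pdk by 0.58 ± 0.0577 and scyl by 0.36 ± 0.0621. Apoptosis and stress-signalling genes had 9 of 20 higher and 0 lower (12 and 1 adjusted over the list alone; camera adjusted p = 0.000973, and adjusted p = 0.818 with an estimated correlation). The gene puc differed by 0.60 ± 0.0834.

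Cytosolic ribosomal proteins were higher in knockdown flies at 2% O2, with 21 of 86 up and 0 down (51 adjusted over the list alone; camera adjusted p = 3.36e-11, and adjusted p = 0.860 with an estimated correlation), a call that quantile normalisation ended (adjusted p = 0.255). Oxidative phosphorylation was lower, with 46 of 68 down and 1 up (59 and 1 adjusted over the list alone; camera adjusted p = 3.95e-18, and adjusted p = 0.860 with an estimated correlation). ND-23 (-0.45 ± 0.0792) and ND-B14 (-0.82 ± 0.114) were examples. Its score was -0.18, -0.36 and 0.15 in the 3 knockdown libraries, of which replicate 3 also had the lowest relative depth (0.87) and a muscle score of 0.36 against -0.27 and -0.27. TCA-cycle genes had 5 of 21 lower and 2 higher (5 and 2 adjusted over the list alone; camera adjusted p = 0.000505, and adjusted p = 0.860 with an estimated correlation), with scores of -0.11, -0.24 and 0.21. Muscle structural genes had 3 of 27 lower and 0 higher (0 adjusted over the list alone; camera adjusted p = 0.00456, and adjusted p = 0.860 with an estimated correlation), which was lost without knockdown 2% O2 replicate 1 (adjusted p = 0.151). Apart from Tudor-SN, the largest single differences included CG11619 (3.48 ± 0.222), CG32198 (3.39 ± 0.503) and CG12506 (2.99 ± 0.213) upward, and Est-6 (-2.32 ± 0.141) and the fatty acid synthase FASN3 (-2.01 ± 0.210) downward. In all, 2000 genes were called (1157 higher, 843 lower, 98 and 60 of them at least 2-fold), and 1900 had groups that did not overlap. The higher share was 57.9%, and 43.6% with FPKM as deposited. The count was 1202 without control 2% O2 replicate 1 and 1977 without knockdown 2% O2 replicate 3.

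**Figure D3:**
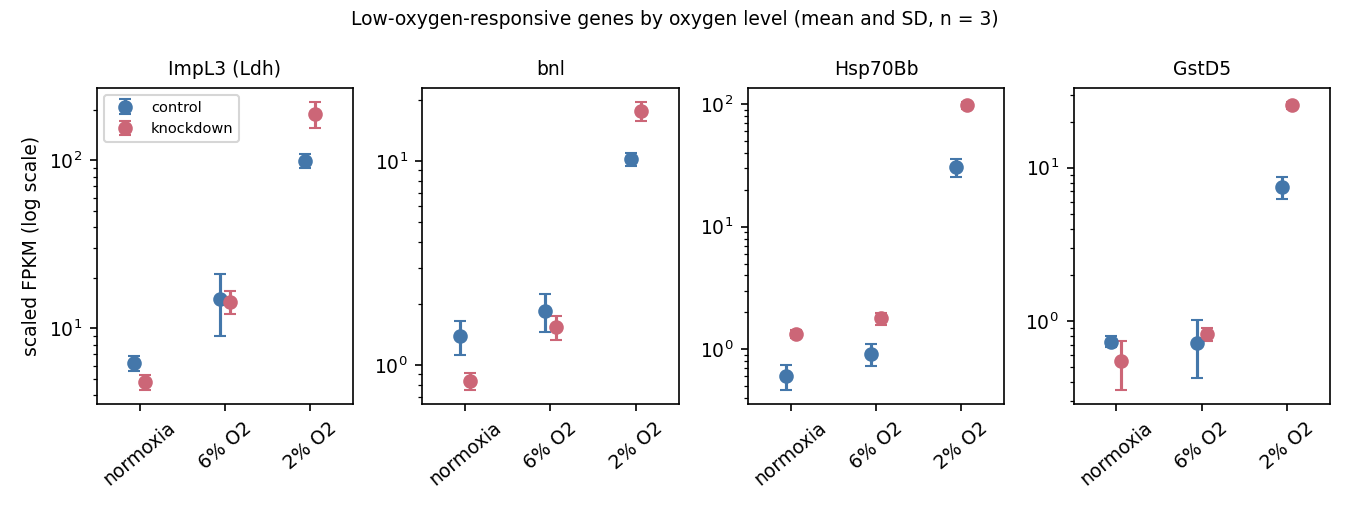
Levels of ImpL3, bnl, Hsp70Bb and GstD5 in scaled FPKM on a log scale (vertical axes) by oxygen level (horizontal axes) for control and knockdown flies. Points are means and bars the SD of 3 libraries. ImpL3 is at 99.4 ± 9.12 in control and 190 ± 33.1 in knockdown flies at 2% O2, and GstD5 at 7.46 ± 1.24 and 25.6 ± 1.31.

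Within knockdown flies, 6% O2 raised some immune peptides and lactate dehydrogenase. ImpL3 rose by 1.41 ± 0.198 (limma adjusted p = 0.00532), a call kept when any single library was left out. Antimicrobial and Toll or Imd target genes had 8 of 35 members up and 0 down (18 and 2 adjusted over the list alone; camera adjusted p = 6.9e-20, and adjusted p = 0.201 with an estimated correlation), with immune scores of -1.06, -0.33 and -0.86 in normoxia. Ribosome biogenesis was lower as a list (0 members called, 1 down adjusted over the list alone, camera adjusted p = 1.79e-10, and adjusted p = 0.201 with an estimated correlation). Gut enzymes were higher as a list (0 called, 6 up adjusted over the list alone, camera adjusted p = 6.36e-07, and adjusted p = 0.471 with an estimated correlation), as were endoplasmic-reticulum genes (1 called, 5 up adjusted over the list alone, camera adjusted p = 1.84e-05, and adjusted p = 0.201 with an estimated correlation). In all, 62 genes were called, 58 higher and 4 lower, of which 39 rose at least 2-fold, and all 62 had groups that did not overlap. The higher share was 93.5%, but 82.7% with quantile normalisation, 76.9% with only the groups compared, 67.1% with array weights and 72.2% without knockdown 6% O2 replicate 1. The 4 lower ones were CG9505 (-0.97 ± 0.164), CG8628 (-1.29 ± 0.247), CG3348 (-0.87 ± 0.182) and CG4753 (-0.22 ± 0.0438). The count was 9 without knockdown normoxia replicate 1 or knockdown 6% O2 replicate 3, 10 and 39 without knockdown normoxia replicates 3 and 2, and 18 without knockdown 6% O2 replicate 1. Each of the 4 lower genes lost its call under at least one of these omissions, since 0 genes were called lower without knockdown normoxia replicates 1 or 3 or knockdown 6% O2 replicate 3.

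Within knockdown flies, 2% O2 moved 5499 of the 9921 genes tested, with chaperones, antioxidant enzymes and immune genes among the rises. ImpL3 rose from 4.79 ± 0.470 to 190 ± 33.1 scaled FPKM (log2 5.03 ± 0.198, limma adjusted p = 2.03e-10). CG34040 rose by 6.22 ± 0.566, Fst by 5.50 ± 0.610, bnl by 3.34 ± 0.117 and the Hsp70 copies by between 5.29 (Hsp70Ba) and 5.97 (Hsp70Bbb). Heat-shock genes had 17 of 24 up and 2 down (17 and 2 adjusted over the list alone; camera adjusted p = 2.14e-07, and adjusted p = 0.150 with an estimated correlation). Oxidative-stress genes had 25 of 35 up and 0 down (25 adjusted over the list alone; camera adjusted p = 1.05e-08, and adjusted p = 0.150 with an estimated correlation). GstD5 changed by 4.11 ± 0.132. Cytochrome P450 genes had 41 of 68 up and 5 down (41 and 5 adjusted over the list alone; camera adjusted p = 6.75e-05, and adjusted p = 0.616 with an estimated correlation). Cyp309a1 changed by 3.42 ± 0.193. Antimicrobial and Toll or Imd targets had 22 of 35 up and 2 down (23 and 2 adjusted over the list alone; camera adjusted p = 0.00718, and adjusted p = 0.684 with an estimated correlation). The Imd inhibitor pirk changed by 2.29 ± 0.169. The immune score was 1.77 in replicate 1 and 0.26 and 0.13 in replicates 2 and 3.

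Translation and germline genes moved in knockdown flies at 2% O2 as well. Cytosolic ribosomal proteins had 81 of 86 up and 1 down (81 and 1 adjusted over the list alone; camera adjusted p = 5.1e-13, and adjusted p = 0.559 with an estimated correlation). RpL11 changed by 0.49 ± 0.0616, and quantile normalisation ended the list's call (adjusted p = 0.257). Ribosome biogenesis had 27 of 32 down and 3 up (27 and 3 adjusted over the list alone; camera adjusted p = 5.31e-09, and adjusted p = 0.176 with an estimated correlation). RpI135 changed by -0.88 ± 0.0501. Stress-granule and mRNA-decay genes had 18 of 23 down and 2 up (19 and 2 adjusted over the list alone; camera adjusted p = 6.65e-05, and adjusted p = 0.343 with an estimated correlation). The gene rin changed by -0.94 ± 0.0747, Upf2 by -0.89 ± 0.0823 and the helicase bel by -0.70 ± 0.0754. Female germline genes had 23 of 41 down and 3 up (23 and 3 adjusted over the list alone; camera adjusted p = 0.000571, and adjusted p = 0.616 with an estimated correlation). The gene orb changed by -1.19 ± 0.0917. Eggshell genes had 10 of 25 down and 0 up (9 adjusted over the list alone; camera adjusted p = 0.00736, and adjusted p = 0.616 with an estimated correlation), a call that quantile normalisation (adjusted p = 0.0595) and array weights (adjusted p = 0.0691) ended. Of the genes called, 2825 were higher and 2674 lower (651 and 151 of them at least 2-fold), and 5332 had groups that did not overlap. The higher share was 51.4%, 41.3% with FPKM as deposited and 38.6% with quantile normalisation. Between 2% O2 and 6% O2 5126 genes were called (2597 higher, 2529 lower at 2% O2), among them ImpL3 (3.62 ± 0.198) and Send1 (-2.88 ± 0.223). The higher share there was 50.7%, and 39.2% and 40.6% under the other scalings.

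The response to 2% O2 was larger in knockdown flies for some chaperones and antioxidant genes and for ImpL3, as tested by the difference of the log2 changes. Hsp70Ba went from 0.421 ± 0.0512 to 17.4 ± 3.27 scaled FPKM in control flies and from 0.433 ± 0.0583 to 55.3 ± 2.47 in knockdown flies. The log2 changes of Hsp70Ba differed by 1.61 ± 0.185 (limma adjusted p = 0.000221). Heat-shock genes had 12 of 24 members with a larger rise and 0 with a smaller one (13 adjusted over the list alone; camera adjusted p = 1.34e-07, and adjusted p = 0.132 with an estimated correlation). The small heat-shock gene Hsp22 (1.40 ± 0.135) was an example. Oxidative-stress and glutathione genes had 13 of 35 higher and 0 lower (20 adjusted over the list alone; camera adjusted p = 1.08e-10, and adjusted p = 0.0877 with an estimated correlation). GstD5 differed by 1.83 ± 0.187 and GstE7 by 0.96 ± 0.0851. Apoptosis and stress-signalling genes had 8 of 20 higher and 0 lower (10 adjusted over the list alone; camera adjusted p = 0.000429, and adjusted p = 0.507 with an estimated correlation). Hypoxia-response genes had 4 of 18 higher and 0 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.00303, and adjusted p = 0.507 with an estimated correlation). The gene bnl differed by 1.10 ± 0.165 and Pdk by 0.56 ± 0.0816. The ImpL3 difference was 1.23 ± 0.280 (adjusted p = 0.0186) and lost its call without control 2% O2 replicate 1 (adjusted p = 0.052) and with quantile normalisation (adjusted p = 0.0546).

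Other groups also differed in their response to 2% O2. Some of these lists already differed between genotypes in normoxia, in the opposite direction. Cytochrome P450 and cytosolic ribosomal protein genes were called lower there, and stress-granule and female germline genes higher. Those starts enter their differences. Cytochrome P450 genes had 15 of 68 higher and 1 lower (18 and 2 adjusted over the list alone; camera adjusted p = 4.2e-05, and adjusted p = 0.673 with an estimated correlation). Cyp309a1 differed by 2.16 ± 0.272. Stress-granule and mRNA-decay genes had 4 of 23 lower and 0 higher (6 and 2 adjusted over the list alone; camera adjusted p = 0.000146, and adjusted p = 0.507 with an estimated correlation). The gene rin differed by -0.52 ± 0.106. Ribosome biogenesis had 5 of 32 lower and 0 higher (7 adjusted over the list alone; camera adjusted p = 0.000146, and adjusted p = 0.550 with an estimated correlation). Female germline genes had 5 of 41 lower and 0 higher (5 and 1 adjusted over the list alone; camera adjusted p = 0.00303, and adjusted p = 0.850 with an estimated correlation). The gene orb differed by -0.58 ± 0.130. Cytosolic ribosomal proteins had 6 of 86 higher and 0 lower (56 adjusted over the list alone; camera adjusted p = 1.59e-14, and adjusted p = 0.673 with an estimated correlation). Their median difference of 0.26 was 0.21 with FPKM as deposited and about 0 with quantile normalisation, which ended the call (adjusted p = 0.828).

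In all, 758 genes were called in the 2% O2 difference, 539 with a higher and 219 with a lower change in knockdown flies. The higher share was 71.1%, 58.8% with FPKM as deposited and 44.8% with quantile normalisation. Over the 2988 genes called in control flies the slope of the knockdown change on the control change was 1.23 (1.21 and 1.17 under those scalings). The change was larger in knockdown flies for 2205 of them (73.8%). The count of 758 was 1295 without knockdown 2% O2 replicate 2 and 454 without replicate 3. It was 337 without control 2% O2 replicate 1, 417 and 370 without control normoxia replicates 1 and 3, and 414, 478 and 425 without knockdown normoxia replicates 1, 2 and 3. The response to 6% O2 gave 0 called differences between genotypes by limma (1017 at an unadjusted p under 0.05). There the oxidative phosphorylation list differed by a median of 0.29 (0 members adjusted over the list alone, camera adjusted p = 1.57e-18, and adjusted p = 0.809 with an estimated correlation). That list was already lower in knockdown flies in normoxia, and this start enters the difference. Ribosome biogenesis differed by -0.17 (10 lower adjusted over the list alone, camera adjusted p = 5.48e-15, and adjusted p = 0.217 with an estimated correlation) and the immune list by 0.80 (7 higher adjusted over the list alone, camera adjusted p = 3.26e-06, and adjusted p = 0.809 with an estimated correlation).

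**Figure D4:**
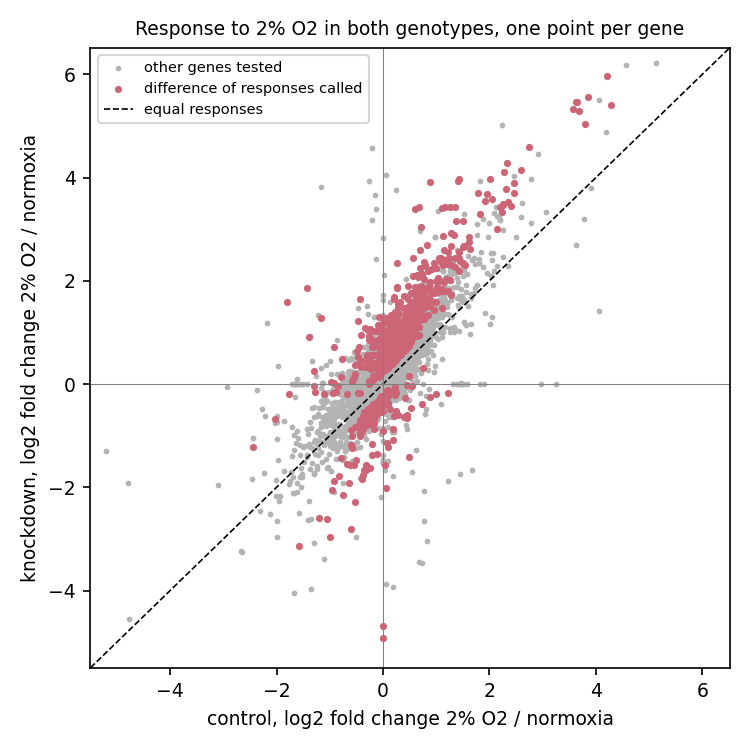
Log2 change from normoxia to 2% O2 in control flies (horizontal axis) and knockdown flies (vertical axis), one point per gene tested. Coloured points are the 758 genes whose changes differed between genotypes, and the dashed line marks equal changes. Over the 2988 genes called in control flies the slope is 1.23, and 2 coloured points far below 0 near the vertical axis are small nucleolar RNAs listed at 0 in every control library.

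Genotype differences at the 3 oxygen levels, which share no libraries, overlapped. In normoxia and 6% O2 294 genes were called higher and 482 lower at both, where independent lists give 70.4 and 127, and 4 were called in opposite directions (195 for independent lists). In normoxia and 2% O2 472 genes were called in the same direction, 316 of them lower (85.3 for independent lists), and 59 in opposite directions. At 6% O2 and 2% O2 322 were higher and 320 lower at both (139 and 107 for independent lists), and 95 opposite. Across genes, which are not independent replicates, the log2 differences had Pearson r of 0.47, 0.24 and 0.32 and Spearman rho of 0.67, 0.26 and 0.29 in these 3 pairs. At all 3 levels 291 genes were called in one direction, 102 higher and 189 lower, Est-6 and Tudor-SN among the latter, and 22 in mixed directions. The responses to 2% O2 of control and knockdown flies shared 1414 rises and 1186 falls (436 and 393 for independent lists), with 21 genes in opposite directions, Pearson r of 0.77 and Spearman rho of 0.77. The responses to 6% O2 shared 0 calls, since limma called 0 genes in control flies (1329 at an unadjusted p under 0.05), with r of 0.20 and rho of 0.06.

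**Figure D5:**
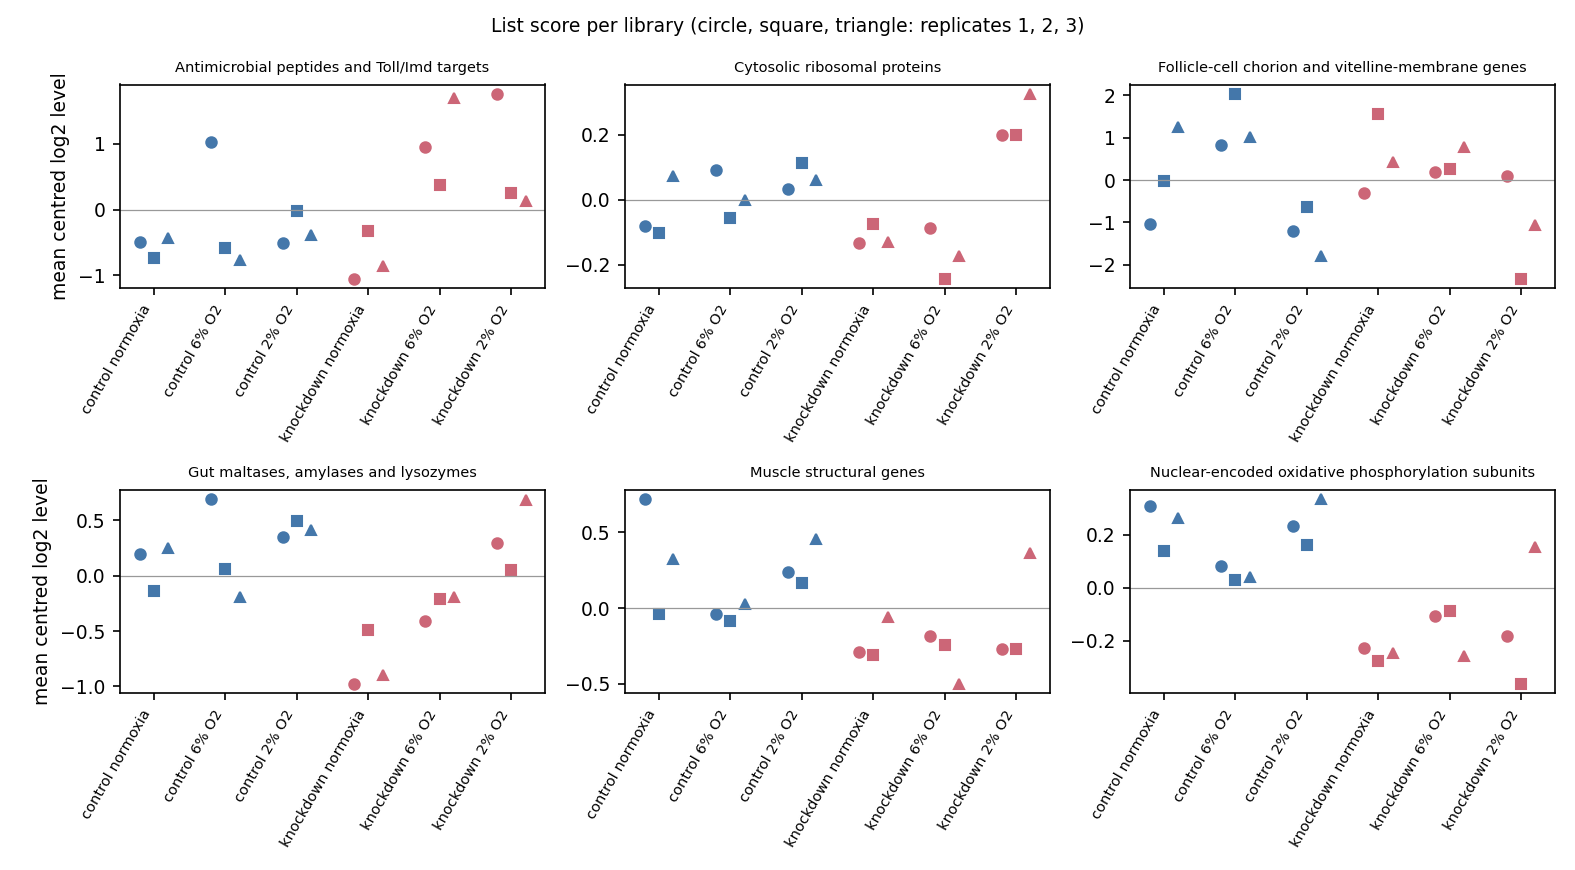
Score of 6 gene lists, the mean centred log2 level of their members (vertical axes), in each library of the 6 groups (horizontal axes). Symbols mark replicates 1, 2 and 3. Knockdown 2% O2 replicate 3 lies above the other knockdown 2% O2 libraries for oxidative phosphorylation (0.15 against -0.18 and -0.36) and muscle (0.36 against -0.27 and -0.27). Control 6% O2 replicate 1 has an immune score of 1.02 against -0.59 and -0.77.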

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

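The tests weighed in this part were chosen after the results were seen, except the test of chromosome 3 and the counts of other splits of the libraries. Every difference of responses listed here met the same criterion, that the change from normoxia to low oxygen differed between knockdown and control flies by limma or, for a list, by camera at its preset correlation.

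In normoxia 64 of 68 oxidative phosphorylation subunits were lower in knockdown flies, among 1589 genes called. The driver lies on chromosome 3, so linked variants of the driver line could place calls there. The odds of a call on chromosome 3 were close to those elsewhere (odds ratio 1.045, 95% interval 0.937 to 1.17, Fisher's exact p = 0.423). Tests by chromosome or arm take genes as independent units, which genes that change together are not. Their p values and intervals therefore do not measure the spread between libraries. At 6% O2 and 2% O2 the ratios were 0.957 and 0.959. This argues against linked variants acting on genes of that chromosome as the main source. Variants that act on genes elsewhere, or the driver itself, would not gather calls there, so the test cannot address them. Arm 3L had the highest share of calls in normoxia, 17.74% against 15.27% to 16.62% on the other arms (odds ratio 1.165, 95% interval 1.02 to 1.33, adjusted p = 0.0911), but ratios of 1.03 and 1.02 at 6% O2 and 2% O2. Linked variants behind some of the calls on that arm are not excluded. Calls were not even over the other arms at low oxygen. On 2L they were more frequent (odds ratio 1.23 at 6% O2 and 1.19 at 2% O2, Fisher's exact adjusted p = 0.00394 and 0.0217). On X they were less frequent (0.789 and 0.819, adjusted p = 0.00394 and 0.0217). The cause was not tested. A smaller share of muscle RNA would lower muscle and mitochondrial genes together. With the muscle score as a covariate the oxidative phosphorylation score still differed by -0.248 (95% interval -0.419 to -0.078), from -0.486 (-0.709 to -0.263) without it. The muscle score itself differed by -0.557 (-0.989 to -0.124). Error in that score as a measure of muscle share would leave part of a muscle effect in place. Whether muscle is the whole cause is therefore not decided. A smaller share of all somatic RNA beside ovary RNA cannot be told apart: this contrast was first run on the fat-body list alone, chosen with library scores in view, and over all 7 somatic lists the oxidative phosphorylation change minus the list's own ran from -0.482 for fat body (-0.828 to -0.136), through -0.279 for neuronal (-0.507 to -0.0516), -0.263 for digestive proteases (-0.672 to 0.146), -0.157 for photoreceptor (-0.390 to 0.0763), 0.0611 for cuticle (-0.224 to 0.346) and 0.0708 for muscle (-0.207 to 0.349), to 0.404 for gut enzymes (-0.0203 to 0.829). An effect of the loss of Tudor-SN itself stays open and was not tested apart from the driver.

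The response to 2% O2 was larger in knockdown flies, with 758 genes called in the difference. Scaling between libraries as the cause of the larger response is argued against by slopes of the knockdown on the control response of 1.21 and 1.17, against 1.23. The fewest calls under any scaling were 745, but a count does not show which response is larger. The direction of the calls moved with the scaling. They were 539 higher and 219 lower, but 438 and 307 with FPKM as deposited and 409 and 504 with quantile normalisation. A stronger exposure or other handling of the knockdown flies at 2% O2 cannot be told apart from a genotype effect: 79.29% of the 758 differences (601, 95% interval 76.2% to 82.1%) had the sign of the control response, as a stronger dose would give, and the sources used here do not describe how the exposures of the groups and replicates were arranged. Control libraries enter both quantities, and their noise pushes toward the opposite sign, so it does not account for this share. The interval of the share takes genes as independent units, which they are not. That Tudor-SN limits the response to low oxygen is a hypothesis that this design leaves untested against handling, the driver or its background.

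Tudor-SN in knockdown flies fell more at 2% O2 than in control flies (-1.32). If this were only the general enlargement of the 2% O2 response, its log2 change would have been -0.43, whereas it was -1.67, a gap of -1.236 (95% interval -1.50 to -0.977), and 4 of 755 other genes with a similar control response fell as far. Scaling is argued against by the smallest difference under another scaling, -1.358. Stronger silencing by the driver and transgene at 2% O2, or lower transcription of Tudor-SN itself, may contribute, and neither was tested.

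With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the real split alone (1 of 10) gave as many calls in each comparison but one. For knockdown against control the real splits gave 1589, 2448 and 2000 genes in normoxia, 6% O2 and 2% O2, and the highest other split 1, 0 and 0. Every other split mixes the groups compared, so a real difference then counts as spread and lowers the calls. The size of the gap therefore does not measure chance. For control flies at 2% O2 they gave 2988 against 1, for knockdown flies at 6% O2 62 against 0 and at 2% O2 5499 against 0, and for 2% O2 against 6% O2 3184 against 1 in control and 5126 against 0 in knockdown flies. For control flies at 6% O2 the real split gave 0 genes by limma (1329 at an unadjusted p under 0.05), all 10 splits gave as many, and the highest other gave 4. For the difference of responses to 6% O2 all 100 splits drawn gave as many as the real 0 (1017 unadjusted), the highest other 8. For that to 2% O2 6 of the 100 drawn gave as many as 758, so chance was not excluded by this count. The highest, 2658, exchanged the genotypes in normoxia but not at 2% O2, which adds the genotype differences of both oxygen levels, and 3 others (1196, 1110 and 1055) also had the normoxia genotypes wholly or mostly exchanged against 2% O2, a structure of the samples. The split with 770 kept the genotypes in normoxia and exchanged 1 library of each genotype at 2% O2, so it lay close to the real one.

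Genes with a larger rise in knockdown flies at 2% O2 were, by difference of log2 changes, Hsp70Aa (1.83), Hsp70Ab (1.83), Hsp70Ba (1.61), Hsp70Bb (1.11), Hsp70Bbb (1.76), Hsp70Bc (1.72), Hsp22 (1.40), ImpL3 (1.23), bnl (1.10), GstD5 (1.83), GstE3 (1.88), Cyp12d1-d (1.53), Cyp12d1-p (1.54), Cyp309a1 (2.16), pirk (1.50), Socs36E (1.16), Gadd45 (1.02), Tps1 (1.19), CG11619 (2.76), CG12506 (2.79) and Pcp (1.11). Higher in the difference were also CG3819 (3.39), CG6839 (3.29), CG32302 (3.04), Mal-A1 (1.73), LysD (1.35), Jon74E (1.58) and Ser8 (1.22). Of these, CG3819, CG6839 and Mal-A1 were already lower in knockdown than in control flies in normoxia, as were gut enzymes as a list. That lower start enters their differences. Lower were CG11741 (-2.07), CG31681 (-1.98), CG8562 (-2.20), the copper importer Ctr1B (-1.76) and Tudor-SN (-1.32). Ctr1B already stood higher in knockdown than in control flies in normoxia, and that higher start enters its difference. Without control 2% O2 replicate 1 the calls of ImpL3 (adjusted p = 0.052), CG32302 (0.0743), Gadd45 (0.0705), Pcp (0.0622) and Mal-A1 (0.109) were lost. CG32302 was also lost without control normoxia replicates 1 and 3 (0.0588 and 0.0669), knockdown normoxia replicates 1 and 3 (0.0654 and 0.0656) and knockdown 2% O2 replicates 1 and 3 (0.0508 and 0.0539). Gadd45 was also lost without control normoxia replicate 3 (0.0678), knockdown normoxia replicate 1 (0.0554) and knockdown 2% O2 replicate 3 (0.053), and Pcp without control normoxia replicate 1 (0.0538) and knockdown normoxia replicate 2 (0.0523). Mal-A1 was lost on leaving out any of 10 libraries, with adjusted p from 0.0594 (knockdown 2% O2 replicate 1) to 0.115 (control normoxia replicate 3), so that only omitting control normoxia replicate 2 or knockdown 2% O2 replicate 2 kept it.

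Lists whose change at 2% O2 differed had these median differences: antimicrobial peptides 0.73, apoptosis and stress signalling 0.24, cytochrome P450 0.31, heat shock 0.45, hypoxia response 0.23, oxidative stress 0.29, gut enzymes 0.88, cytosolic ribosomal proteins 0.26 (0.21 with FPKM as deposited and about 0 with quantile normalisation), ribosome biogenesis -0.12, female germline -0.10, small-RNA genes -0.16 and stress granule -0.17, with adjusted p from 0.0877 to 0.886 with an estimated correlation. In normoxia the gut enzyme, cytochrome P450, cytosolic ribosomal protein, glycolysis and oxidative phosphorylation lists were already called lower in knockdown flies. Those of female germline, small-RNA and stress-granule genes were called higher there. These starts enter the differences. Cell-cycle genes (-0.11), glycolysis (0.0412, and -0.01 and -0.04 under the other scalings) and oxidative phosphorylation (0.12) were called too. Without knockdown 2% O2 replicate 3 these 3 calls were lost (adjusted p = 0.361, 0.816 and 0.202, the last with the opposite sign). Cell cycle was lost as well without control normoxia replicates 1 and 3 (0.0525 and 0.177), control 2% O2 replicate 1 (0.0622) and knockdown normoxia replicate 1 (0.068), glycolysis without control normoxia replicates 1 and 2 (0.0577 each), control 2% O2 replicate 2 (0.0994) and knockdown normoxia replicate 2 (0.1), and oxidative phosphorylation without control normoxia replicates 1 and 3 (0.241 and 0.0778), control 2% O2 replicates 1 and 2 (0.0618 and 0.29) and knockdown normoxia replicate 2 (0.137).

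For the response to 6% O2 the median differences were antimicrobial peptides 0.80, cytosolic ribosomal proteins -0.11, ribosome biogenesis -0.17, endoplasmic-reticulum genes 0.10, eggshell -0.997, glycolysis 0.15, oxidative phosphorylation 0.29 and TCA cycle 0.23, with adjusted p from 0.217 to 0.85 with an estimated correlation. The oxidative phosphorylation, TCA-cycle, glycolysis, cuticle and gut enzyme lists were already called lower in knockdown flies in normoxia, and small-RNA genes higher. These starts enter their differences. Called as well were cuticle 0.23, cell cycle 0.12, digestive proteases -0.19, gut enzymes 0.34, small-RNA genes -0.0397 and yolk proteins -0.57, with adjusted p from 0.538 to 0.97 with an estimated correlation. Calls of these last 6 lists were lost on leaving out single libraries. Gut enzymes were lost without control 6% O2 replicates 2 and 3 (0.0622 and 0.188) and knockdown normoxia replicate 1 (0.0699), yolk without control normoxia replicate 1 (0.0604) and control 6% O2 replicate 2 (0.0533), and cell cycle without control normoxia replicate 2 (0.34), control 6% O2 replicate 1 (0.773) and knockdown 6% O2 replicate 2 (0.129). Cuticle was lost without control normoxia replicates 1 and 3 (0.377 and 0.143), control 6% O2 replicate 2 (0.36), knockdown normoxia replicates 1 and 2 (0.102 and 0.0508) and knockdown 6% O2 replicate 1 (0.286). Small-RNA genes were lost without control normoxia replicates 1 and 3 (0.0604 and 0.128), control 6% O2 replicates 2 and 3 (0.0894 and 0.0926), knockdown normoxia replicates 1 and 3 (0.057 and 0.066) and knockdown 6% O2 replicates 1 and 3 (0.0996 and 0.0525). Digestive proteases were lost without control normoxia replicate 2 (0.653), control 6% O2 replicates 1 and 2 (1 and 0.0894), knockdown normoxia replicates 2 and 3 (0.484 and 0.056) and knockdown 6% O2 replicates 2 and 3 (0.13 and 0.0709).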

How the results depend on the processing

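All alternatives were set before the values were seen except the one without loci under 300 bp, which moved no count of called genes past 1.5 times. Tudor-SN was lower in knockdown flies at every oxygen level under every alternative. Between knockdown and control flies the fit of only the groups compared gave 1354 genes at 6% O2 and 1204 at 2% O2, against 2448 and 2000. In normoxia that fit gave 1489 against 1589. Fewer libraries then estimate the spread, and the spread of these groups may differ from the shared one. Which of these lowered the counts was not tested. Array weights gave 3414 in normoxia, 3898 at 2% O2, 386 for knockdown flies at 6% O2 against normoxia, 107 for the difference of responses to 6% O2 and 2371 for that to 2% O2, and the cause was not tested. For control flies at 6% O2 there was 1 gene with no filter, 2 with only the groups compared and 25 with quantile normalisation, which also gave 27 for the difference of responses to 6% O2 and 4 calls of the same sign at 6% O2 in both genotypes. A mean of at least 5 FPKM gave 5 for that difference. Of 172 list calls 0 were left with an estimated correlation and 92 with fry, which called 102 in all.

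Leaving out 1 library at a time gave these ranges. For knockdown against control they were 607 to 2244 in normoxia, 887 to 2725 at 6% O2 and 1202 to 1977 at 2% O2. For control flies they were 0 to 5 at 6% O2, 2348 to 2644 at 2% O2 and 2397 to 2866 for 2% O2 against 6% O2. For knockdown flies they were 9 (without knockdown normoxia replicate 1 or knockdown 6% O2 replicate 3) to 90 (without knockdown 6% O2 replicate 2) at 6% O2, 4803 to 5482 at 2% O2 and 4436 to 5079 for 2% O2 against 6% O2. They were 0 to 11 (without knockdown 6% O2 replicate 2) for the difference of responses to 6% O2, 337 (without control 2% O2 replicate 1) to 1295 (without knockdown 2% O2 replicate 2) for that to 2% O2, and 162 to 181 for list calls. Fewer libraries also lower the power of the test.

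Some list results turned. The ribosomal protein list in normoxia turned with quantile normalisation (adjusted p = 0.437) and, in control flies at 6% O2, with array weights (0.683). In control flies at 6% O2 the neuronal and photoreceptor lists turned without control normoxia replicate 2 (0.00504 and 0.0152, ranges over all omissions 0.00391 to 0.854 and 0.0144 to 0.503). There the immune and digestive protease lists turned without control 6% O2 replicate 1 (0.714 and 0.0081, ranges 0.00200 to 0.714 and 0.00119 to 0.702). The oxidative phosphorylation list turned without knockdown 2% O2 replicate 3 for 2% O2 against 6% O2 in knockdown flies (0.00183, range up to 0.737) and for the difference of responses to 2% O2 (0.202, range 1.04e-06 to 0.29). The cause was not tested. Of named genes, 624 results lost and 61 gained a call on leaving out a library, and 7966 stayed on the same side of the threshold, called or not. Under the other settings 229 lost and 186 gained one, and 12973 stayed. Of lists, 125 lost and 98 gained a call and 2345 stayed on leaving out a library, against 346, 89 and 4282 under other settings.

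Replicate numbers did not pair the libraries. Deviations from group means had a mean correlation of -0.0143 for libraries with the same number (from -0.325 to 0.25, 11 of 45 pairs over 0.1) and 0.00724 for others (28 of 90 over 0.1). With the replicate block, 31 genes were called for knockdown flies at 6% O2, against 62. Low relative depth (0.87) limits low genes in knockdown 2% O2 replicate 3, and the absence of read totals leaves counting error unknown.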

Other observations

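The genes in this part come from the rule stated for named genes or, where said, were picked after their values were seen. The basement-membrane collagen genes vkg and Col4a1, expressed in fat body and haemocytes, were lower at 2% O2 than in normoxia. In control flies at 2% O2 vkg changed by -1.59 ± 0.121 and Col4a1 by -1.35 ± 0.124, and in knockdown flies vkg by -1.05 ± 0.121. Knockdown flies at 6% O2 had less of both than control flies (vkg -0.72 ± 0.121, Col4a1 -0.64 ± 0.124). The haemocyte list itself was not called in control flies at 2% O2 (4 members up and 4 down). Single metal genes differed too, while the metal and iron list was not called in any comparison (camera adjusted p from 0.134 to 0.814). The secreted ferritin subunits rose at 2% O2 in control flies (Fer1HCH 0.59 ± 0.0804, Fer2LCH 0.57 ± 0.0878), and Fer1HCH also rose in knockdown flies (1.07 ± 0.0804). The metallothionein MtnE was lower in knockdown flies in normoxia (-1.93 ± 0.343) while the copper importer Ctr1B was higher (1.92 ± 0.214), and Ctr1B was also higher at 6% O2 (1.48 ± 0.214).

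Clock and signalling genes gave further differences. The clock neuropeptide Pdf was lower in knockdown flies in normoxia (-0.79 ± 0.110) and at 6% O2 (-0.76 ± 0.110), as was the adipokinetic hormone gene Akh in normoxia (-1.17 ± 0.267). At 2% O2 the clock repressor vri rose by 1.39 ± 0.131 and the clock output to by 1.14 ± 0.0978 in knockdown flies, and the rise of vri was larger than in control flies by 0.95 ± 0.185. The odorant-binding protein gene Obp99b rose in control flies at 2% O2 (1.63 ± 0.261) and stood lower in knockdown than in control flies there (-1.25 ± 0.261), whereas Obp99a stood higher (1.82 ± 0.281). The JAK/STAT feedback gene Socs36E rose in control flies at 2% O2 (1.51 ± 0.169) and stood higher still in knockdown flies (0.94 ± 0.169).

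Small nucleolar RNAs snoRNA:Psi18S-920 and snoRNA:Psi28S-2149 were listed at 0 in all control libraries and in all knockdown libraries at 2% O2. In knockdown flies in normoxia the first had 19.3, 62.3 and 21.8 FPKM and the second 16.4, 52.4 and 18.3, and at 6% O2 they had 22, 20.4 and 0, and 18.5, 0 and 0. They are short loci in libraries selected for polyadenylated RNA, where FPKM is unstable, and no fold is given.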
